A study of Mus musculus with 16 samples.

How the data were processed

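The deposited table held 16 columns, 1 per library, with 53647 genes by Ensembl identifier. Per the file's name and its values, the deposited log2 values were made by the authors as log2 of TPM plus 1, TPM being transcript abundance scaled to transcript length and to the library's total. Turned back to TPM, each column summed to between 999999.12 and 1000000.8 TPM, and each value lay within 2.3e-09 TPM of a multiple of 0.01 TPM. Per the submitters' processing notes, reads were aligned with STAR and quantified with RSEM against the mouse genome GRCm39 (mm39), with no versions, annotation release or strand setting given. RNA came from a column kit (RNeasy mini plus, Qiagen) and libraries were made from 0.6 ug of total RNA, per the labels. Groups, batches and replicate numbers were read from the sample titles. Symbols were taken from an annotation of an earlier mouse build, GENCODE M21 on GRCm38, so no coordinates are given. In all, 52093 identifiers matched a symbol and 1554 did not; the unmatched ones held between 0.299% and 3.59% of a library's TPM, most of it in 1 identifier (0.232% to 3.54%).

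Read counts were not used here, so no count model was fitted. The test was limma with a trended prior variance on log2(TPM + 1), fitted to all 16 libraries with 4 group means and batch as a term, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes entered with at least 1 TPM in at least 4 libraries, which left 17003. Quoted SE are those of the moderated fit. Within-batch values are differences of group means of log2(TPM + 1) inside a batch, over 2 libraries per group, without a test. Whether an effect differed between batches was tested as an interaction in a fit with 8 group-by-batch means. For Atp12a an exact two-sided permutation test over 70 relabellings of 8 libraries was added, which ignores batch. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

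Gene groups were 41 lists of matrix, inflammation, epithelial, endothelial, stress, pump and cell type genes, with lists for blood, heart, skeletal muscle, fat and sex as checks of other tissue in a sample. Lists with at least 4 genes tested entered, which was 40; the list of basal and squamous markers had too few. The list test was limma's camera with its preset correlation of 0.01 between genes, adjusted over the lists of one comparison, and it compares a list with all other genes. Camera with an estimated correlation and fry were alternatives; fry asks whether a list's genes move one way on balance and does not compare a list with other genes. For each list the number of members past the threshold is given over all genes and adjusted over the list alone. The median log2 fold change of all genes tested in bleomycin against control was 0.05, and no scaling moved the median of any comparison by more than 0.1.

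The tests, lists, filter and alternatives, except those named as later, were chosen before the data were examined. Named genes followed a rule set then: Atp12a; the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in both batches, or all where there were fewer; for each list described, up to 4 members with the smallest p; members needed to say which did not pass; and where fewer than 10 genes passed, the 5 genes with the smallest p. Passed over in naming, but counted, were predicted models, identifiers without a symbol, pseudogenes and immunoglobulin or T cell receptor segments. Igkv4-72 lies outside this rule, and the genes named beside the batch differences and the library differences (Xist, Scgb1a1, Scgb3a2, Cyp2f2, Alb and Kng2 among them) were chosen after values were seen.

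Alternatives were a pseudocount of 0.1, no filter, a filter of a mean of 5 TPM, quantile normalization, median-ratio scaling, the 8 libraries compared alone, no batch term, a replicate block, array weights, a robust prior, each batch alone, a minimum absolute log2 fold change of 1, and each library left out in turn. A term for Xist-expressing libraries and a fit without the 3 libraries low in Scgb1a1 were added after the data were seen.

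A self-test simulated each gene with its own mean, batch difference and residual spread and no group difference. It planted 100 changes per fold size and ran the same tests over 17003 genes. In the order of the Results, the 4 comparisons recovered 80, 71, 78 and 63 of 100 genes at a log2 change of 1. At 2 they recovered 96, 95, 91 and 96. Unchanged genes called numbered 11, 13, 8 and 10. A planted list was found in all 4. Of 100 effects 4 log2 units apart between batches, 95, 97, 89 and 96 were recovered. With uncorrelated genes and many planted changes, which ease the threshold, these shares do not carry over to comparisons where few genes passed.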

Results

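RNA was sequenced from mouse lungs in 4 groups: control, bleomycin, bleomycin with an adenovirus carrying GFP (Ad-GFP), and bleomycin with an adenovirus named for ATP12A (Ad-ATP12A). Bleomycin is a drug that injures the lung and is used to model pulmonary fibrosis in mice. ATP12A is the alpha subunit of the non-gastric proton-potassium pump, and the series title names it as a target in idiopathic pulmonary fibrosis. Each group had 4 libraries, 2 from each of 2 batches, which made 16 libraries. A library is written here by its batch and replicate, so b1r2 is batch 1, replicate 2. The labels give no sex, dose, day of collection or species of the transgene. They also do not state that replicates were separate animals, so the p-values of single genes below measure the spread between libraries. Camera's p-values with the preset correlation weigh a list's genes against all other genes, and a small one does not measure that spread.

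Values were TPM, transcript abundance scaled to transcript length and to the library's total, a unit that keeps no read counts, so the depth of each library is unknown. The libraries held between 15537 and 16336 genes at 1 TPM or more. Their 10 most abundant genes took between 12% and 25.8% of the TPM, and mitochondrially encoded genes took between 5.31% and 11.5%. The lowest correlation between libraries of one group was r = 0.929 across genes, and no libraries were identical. Group values are means ± SD over 4 libraries. Fold changes are on the log2(TPM + 1) scale from the limma fit with batch as a term, over 17003 genes tested.

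Libraries differed within groups in ways that the labels do not give. Xist, the RNA made from the inactive X chromosome in female cells, reached at least 10 TPM in 6 libraries: 1 control, 1 bleomycin, 1 Ad-GFP and 3 Ad-ATP12A. Scgb1a1, the main secretory protein of club cells, lay under 1000 TPM in 3 libraries, with 441 TPM in control b2r1, 128 TPM in bleomycin b2r2 and 295 TPM in Ad-GFP b1r1. The other 13 libraries held between 24870 and 122337 TPM of Scgb1a1, and no Ad-ATP12A library was low. These imbalances stand beside each comparison below.

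Atp12a (ENSMUSG00000022229, on chromosome 14) was near 0 in every lung without the Ad-ATP12A vector. It measured 0.0275 ± 0.0359 TPM in control, 0.0525 ± 0.0984 TPM in bleomycin and 0.0175 ± 0.0236 TPM in Ad-GFP lungs. Ad-ATP12A lungs held 15.7 ± 13.6 TPM of it. The 2 batches differed in level: Ad-ATP12A libraries of batch 1 had 5.13 and 2.96 TPM, and those of batch 2 had 29.02 and 25.70 TPM. A transgene from another species would be read only in part by the mouse gene, so these levels describe mouse-matching reads.

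**Figure D1:**
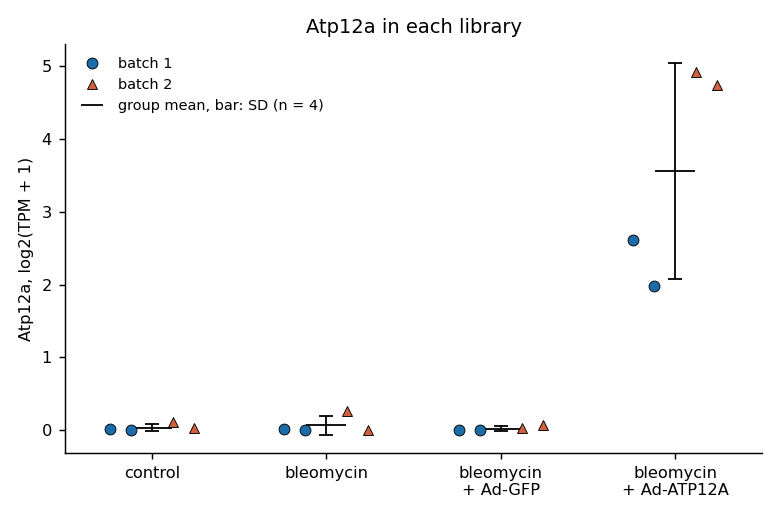
Atp12a per library, as log2(TPM + 1), in the 4 groups, with points marked by batch and bars for the group mean ± SD. The 4 Ad-ATP12A libraries lie between 2.96 and 29.02 TPM and the other 12 libraries between 0 and 0.20 TPM.

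Bleomycin against control asks what the injury did to the lung. Bleomycin lungs held several-fold more transcripts of scar matrix, of the macrophages found in scars and of dividing cells, with Col3a1, a fibrillar collagen, at 735 ± 162 against 91.0 ± 24.3 TPM. Transcripts of capillary endothelium, of mesothelium, the lining of the lung surface, and of red blood cells were lower as lists, with 3 of 11, 5 of 7 and 5 of 6 genes past the limma test and adjusted p = 0.373, 0.243 and 0.358 with an estimated correlation. In all, 3201 of the 17003 genes passed the test, 2247 higher and 954 lower, and all 3201 had the same sign in both batches. Atp12a did not pass (log2 fold change 0.03, SE 0.424, adjusted p = 0.972; exact permutation p = 0.971, two-sided).

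Among the largest rises, Mmp12, the macrophage elastase, rose from 13.3 ± 2.59 to 718 ± 457 TPM (log2 fold change 5.38, SE 0.846, adjusted p = 0.00127). Tnc, the matrix protein tenascin C, rose from 2.90 ± 0.965 to 87.2 ± 27.5 TPM (4.47, SE 0.583, adjusted p = 3.6e-04). Timp1, an inhibitor of matrix metalloproteinases, rose by 4.42 (SE 0.758, adjusted p = 0.00223), and Eln, the gene of elastin, by 3.82 (SE 0.460, adjusted p = 2.3e-04). Retnla, a product of alternatively activated macrophages, rose from 318 ± 335 to 5139 ± 3983 TPM (4.12, SE 0.593, adjusted p = 6.9e-04), although the ranges of its groups overlapped. Spp1, which encodes osteopontin, rose from 168 ± 45.2 to 1912 ± 612 TPM (3.48, adjusted p = 0.00216). Saa3, an acute-phase protein, rose by 3.67 (adjusted p = 0.0129), Col1a1 by 3.48 (adjusted p = 0.00217) and Clec4n, a myeloid lectin receptor, by 3.29 (adjusted p = 0.00103). Grem1, an antagonist of bone morphogenetic proteins, rose by 3.24 (adjusted p = 0.0230); its adjusted p was 0.0801, 0.0693 and 0.0519 without bleomycin b1r1, b1r2 and b2r2.

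Among the largest falls, Bex2 fell from 50.2 ± 6.87 to 6.37 ± 4.97 TPM (log2 fold change −3.04, SE 0.542, adjusted p = 0.00274), and Cst8, a member of the cystatin family, fell from 14.9 ± 5.15 to 1.28 ± 0.799 TPM (−2.82, SE 0.346, adjusted p = 2.5e-04). Inmt, an indolamine methyltransferase abundant in lung, fell from 2346 ± 827 to 453 ± 219.6 TPM (−2.41, SE 0.494, adjusted p = 0.00563). Fabp1, a fatty acid carrier, changed by −2.54 (adjusted p = 0.00895), Nrn1 by −2.50 (adjusted p = 0.00186), Ankrd63 by −2.44 (adjusted p = 1.1e-04) and Colq, the collagen tail of acetylcholinesterase, by −2.38 (adjusted p = 0.00562). Hbb-bt, an adult beta-globin whose reads are partly shared with Hbb-bs, changed by −2.23 (adjusted p = 0.00504). Mb, which encodes myoglobin, changed by −2.76 (adjusted p = 0.0490), and its call ended without any one of 10 libraries (adjusted p between 0.0540 and 0.156): control b1r1, b1r2 and b2r2, bleomycin b1r1, b1r2 and b2r2, Ad-GFP b1r2, and Ad-ATP12A b1r1, b2r1 and b2r2. Acoxl changed by −2.67 (adjusted p = 0.0255), and its adjusted p was 0.0715 and 0.0685 without control b1r1 and b1r2, and 0.0931 and 0.0830 without bleomycin b1r1 and b1r2.

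Of the 15 collagen genes, 12 rose and none fell, and 14 rose adjusted over the list alone. Col15a1 rose by 2.57 (SE 0.380, adjusted p = 8.6e-04), and Col3a1 by 3.02 (SE 0.331, adjusted p = 1.3e-04). The list's median log2 fold change was 1.81, with 2.21 in batch 1 and 1.44 in batch 2 (camera adjusted p = 7.6e-08; adjusted p = 0.372 with an estimated correlation). Of 20 matrix glycoproteins and crosslinking enzymes, 14 rose, or 16 adjusted over the list alone, among them Serpinh1, the collagen chaperone, by 1.33 (adjusted p = 2.8e-04). Their median was 1.81, with 1.95 and 1.55 by batch (camera adjusted p = 1.6e-08; adjusted p = 0.372 with an estimated correlation). Of 14 matrix proteases and their inhibitors, 9 rose, or 11 higher and 1 lower adjusted over the list alone, with a median of 1.78 and 1.65 and 1.70 by batch (camera adjusted p = 1.1e-04; adjusted p = 0.373 with an estimated correlation). Mmp19 rose by 2.07 (adjusted p = 6.6e-04) and Mmp2, a gelatinase, by 1.91 (adjusted p = 6.9e-04).

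Of 13 genes of the TGF-beta response, 8 rose and 1 fell, by the test over all genes and adjusted over the list alone. Tgfb3 rose by 0.76 (adjusted p = 0.00321) and Pmepa1 by 1.67 (adjusted p = 0.00487), while Smad7, an inhibitor of the pathway, fell by 0.74 (adjusted p = 0.0113). The list's median was 0.72, with 0.64 and 0.55 by batch (camera adjusted p = 0.0183; adjusted p = 0.460 with an estimated correlation), and in batch 2 alone its camera adjusted p was 0.170.

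Of 15 genes of lipid-handling and scar macrophages, 9 rose, or 10 adjusted over the list alone. Trem2, a lipid-sensing receptor of macrophages, rose from 4.75 ± 0.667 to 53.7 ± 14.6 TPM (3.21, SE 0.329, adjusted p = 1.1e-04). The list's median was 1.60, with 1.53 and 1.47 by batch (camera adjusted p = 9.1e-06; adjusted p = 0.358 with an estimated correlation). Of 11 genes of monocytes and interstitial macrophages, 7 rose, or 9 higher and 1 lower adjusted over the list alone, with a median of 1.31 and 0.98 and 1.79 by batch (camera adjusted p = 4.5e-04; adjusted p = 0.373 with an estimated correlation). C1qb and C1qa, which encode chains of complement C1q, rose by 2.99 (adjusted p = 0.00127) and 2.78 (adjusted p = 0.00148). Of 13 genes of the vacuolar proton pump and lysosome, 8 rose, or 9 adjusted over the list alone, such as Ctss, which encodes cathepsin S, from 262 ± 54.9 to 1442 ± 319 TPM (2.45, adjusted p = 2.6e-04), and Acp5 by 1.94 (adjusted p = 8.3e-04). That list's median was 0.73, with 0.53 and 0.63 by batch (camera adjusted p = 1.9e-05; adjusted p = 0.373 with an estimated correlation).

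All 17 cell cycle genes rose, also adjusted over the list alone, with a median of 2.05 and 2.03 and 1.99 by batch (camera adjusted p = 8.9e-18; adjusted p = 0.243 with an estimated correlation). Cdk1, the kinase of mitotic entry, rose from 5.86 ± 1.92 to 44.8 ± 8.96 TPM (2.77, SE 0.228, adjusted p = 4.6e-05), and Top2a by 2.18 (adjusted p = 6.4e-05). Of 15 genes of the p53 response and senescence, 12 rose by either adjustment, adjusted over the list alone included, with a median of 0.94 and 0.83 and 0.75 by batch (camera adjusted p = 1.5e-08; adjusted p = 0.243 with an estimated correlation). Gdf15, a stress-induced cytokine, rose by 1.51 (adjusted p = 1.2e-04) and Bax, a promoter of cell death, by 0.94 (adjusted p = 1.9e-04). Of 11 markers of transitional alveolar epithelium, the state between the alveolar cell types after injury, 9 rose by either adjustment, adjusted over the list alone included. Sprr1a rose from 0.735 ± 0.566 to 11.8 ± 3.27 TPM (2.90, adjusted p = 1.3e-04), Cldn4 by 3.11 (adjusted p = 0.00212) and Areg, an EGF receptor ligand, by 1.75 (adjusted p = 5.0e-04). The list's median was 0.85, with 1.16 and 0.55 by batch (camera adjusted p = 9.6e-07; adjusted p = 0.358 with an estimated correlation).

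Of 17 inflammatory cytokines and chemokines, 12 rose, or 13 adjusted over the list alone, with a median of 1.22 and 1.47 and 1.22 by batch (camera adjusted p = 5.8e-05; adjusted p = 0.358 with an estimated correlation). Ccl12 and Ccl8, which attract monocytes, rose by 2.90 (adjusted p = 0.00504) and 2.47 (adjusted p = 0.00603), and Il6 rose by 1.22 (adjusted p = 0.00831). Of 18 type I interferon response genes, 10 rose, or 12 adjusted over the list alone, with a median of 1.00 and 1.10 and 0.83 by batch (camera adjusted p = 1.5e-05; adjusted p = 0.376 with an estimated correlation). Isg15 rose by 1.70 (adjusted p = 0.00636), and Oas1a, whose reads are partly shared with other Oas1 genes, by 1.44 (adjusted p = 0.00286). Of 16 genes of the interferon gamma response and MHC class II, 7 rose by either adjustment, adjusted over the list alone included, such as Cxcl10, a chemokine for activated T cells, by 3.01 (adjusted p = 7.7e-04), and H2-Ab1 by 0.85 (adjusted p = 0.0121). This list's median was 0.31, with 0.01 and 0.74 by batch (camera adjusted p = 0.0173; adjusted p = 0.568 with an estimated correlation). Its call ended without control b2r1 (adjusted p = 0.0617), without the 3 libraries low in Scgb1a1 (0.110), in batch 1 alone (0.228) and with array weights (0.0927), and its median was 0.56 without control b1r1, 0.20 without control b2r2 and 0.21 without bleomycin b2r2.

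**Figure D2:**
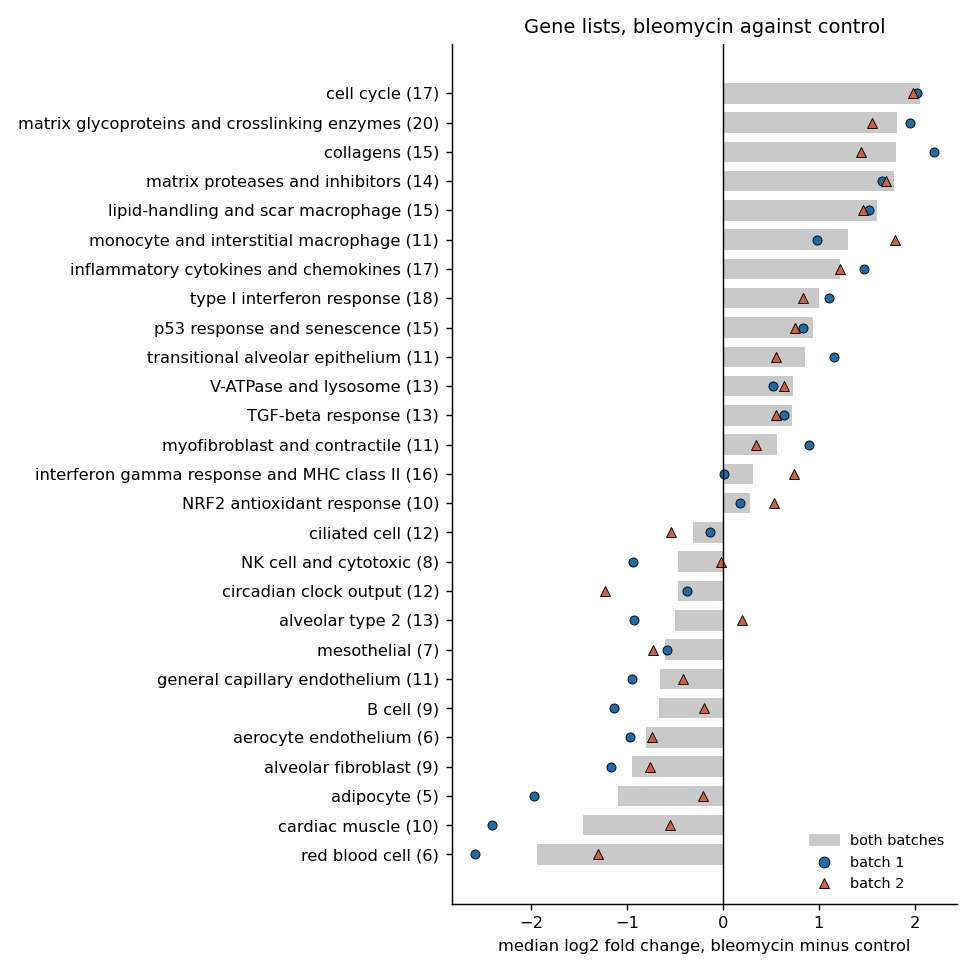
Median log2 fold change of bleomycin against control for the 27 gene lists that passed by camera, as bars with the number of genes tested in brackets, and the medians within batch 1 and batch 2 as points. Cell cycle genes have the highest median, 2.05, and red blood cell genes the lowest, −1.94.

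Lists of vessel, support and blood cells were lower. Of 11 genes of general capillary endothelium, 3 fell, or 8 adjusted over the list alone, with a median of −0.65 and −0.95 and −0.41 by batch (camera adjusted p = 1.2e-04; adjusted p = 0.373 with an estimated correlation). Ptprb, an endothelial phosphatase, fell by 1.18 (adjusted p = 0.0105). Kdr, the main VEGF receptor of endothelium, changed by −1.13 (adjusted p = 0.0201), and its adjusted p was 0.0533 and 0.0606 without control b1r1 and b1r2, and 0.0690 and 0.0677 without bleomycin b1r1 and b1r2. Of 6 genes of aerocytes, the gas-exchange capillary cells, 4 fell, or 5 adjusted over the list alone, such as Fibin by 1.60 (adjusted p = 0.0164; 0.0592 without bleomycin b1r1), with a median of −0.81 and −0.97 and −0.75 by batch (camera adjusted p = 4.6e-04; adjusted p = 0.373 with an estimated correlation). Of 9 genes of alveolar fibroblasts, 3 fell, or 7 adjusted over the list alone, such as Wnt2 by 0.95 (adjusted p = 0.0143; 0.0526 without bleomycin b1r2), with a median of −0.95 and −1.17 and −0.77 by batch (camera adjusted p = 4.5e-04; adjusted p = 0.373 with an estimated correlation). Of 7 mesothelial genes, 5 fell by either adjustment, adjusted over the list alone included, with a median of −0.61 and −0.59 and −0.73 by batch (camera adjusted p = 1.2e-04; adjusted p = 0.243 with an estimated correlation). Gpm6a fell by 1.25 (adjusted p = 5.3e-04) and Lrrn4 by 1.01 (adjusted p = 0.00143).

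Of 6 red blood cell genes, 5 fell, and all 6 adjusted over the list alone, with a median of −1.94 and −2.59 and −1.31 by batch (camera adjusted p = 1.1e-05; adjusted p = 0.358 with an estimated correlation). Hba-a1, an alpha-globin that shares reads with Hba-a2, fell by 1.95 (adjusted p = 0.00434). Of 10 cardiac muscle genes, which mark heart or the muscle sleeve of pulmonary veins, 1 fell, or 8 adjusted over the list alone. This list's median was −1.47, with −2.41 in batch 1 and −0.55 in batch 2 (camera adjusted p = 1.2e-04; adjusted p = 0.373 with an estimated correlation), and in batch 2 alone its camera adjusted p was 0.0609. The member that fell, Ryr2, changed by −0.99 (adjusted p = 0.0338), with adjusted p between 0.0611 and 0.107 without any one of control b1r1, b1r2 and b2r2 and bleomycin b1r1, b1r2 and b2r2. Of 5 adipocyte genes, 1 fell, or 3 adjusted over the list alone, with a median of −1.10 and −1.97 and −0.21 by batch (camera adjusted p = 0.00531; adjusted p = 0.373 with an estimated correlation). The adipocyte median was −0.69 without control b1r1, and in batch 2 alone its camera adjusted p was 0.231.

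Several further lists passed by camera with small shifts, and their calls rested on few libraries. Of 11 myofibroblast and contractile genes, 3 rose by either adjustment, adjusted over the list alone included, with a median of 0.56 and 0.90 and 0.34 by batch (camera adjusted p = 0.0475; adjusted p = 0.568 with an estimated correlation). Fap, a protease of activated fibroblasts, rose by 0.86 (adjusted p = 0.0146; 0.0561 without bleomycin b1r1), and Adam12 by 1.86 (adjusted p = 0.0189; 0.0706 and 0.0586 without bleomycin b1r1 and b1r2). The list's adjusted p lay between 0.0518 and 0.197 without any one of control b1r1, b2r1 and b2r2, bleomycin b1r1, b1r2 and b2r2, and Ad-GFP b1r1 and b2r2, and its median was 0.35 without bleomycin b1r1 and 0.92 without bleomycin b2r1. The NRF2 antioxidant list had 4 of 10 genes higher by either adjustment, adjusted over the list alone included, such as Hmox1 by 1.07 (adjusted p = 0.00653), with a median of 0.28 and 0.18 and 0.53 by batch (camera adjusted p = 0.0446; adjusted p = 0.460 with an estimated correlation). Its adjusted p lay between 0.0576 and 0.119 without any one of control b1r2, b2r1 and b2r2 and bleomycin b1r1 and b2r1, and its median was 0.45 without control b1r1.

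None of the 13 alveolar type 2 genes passed, by limma over all genes or adjusted over the list alone, and their median was −0.50, with −0.93 in batch 1 and 0.20 in batch 2 (camera adjusted p = 0.0274; adjusted p = 0.608 with an estimated correlation). Sftpa1, a surfactant protein, measured 1544 ± 1123 against 3483 ± 1135 TPM (−1.36, adjusted p = 0.106), and it passed without bleomycin b2r1 (adjusted p = 0.0222). The list's call ended without control b1r1 (adjusted p = 0.0708, median −0.27), bleomycin b1r1 (0.196, median −0.28) or bleomycin b1r2 (0.0544). No B cell or NK cell gene passed either, by limma over all genes or adjusted over the list alone. The 9 B cell genes had a median of −0.67, with −1.14 and −0.20 by batch (camera adjusted p = 0.00531; adjusted p = 0.460 with an estimated correlation). The 8 genes of NK and cytotoxic cells had a median of −0.47, with −0.94 and −0.02 by batch (camera adjusted p = 0.0144; adjusted p = 0.383 with an estimated correlation), and their call ended without control b1r1 (adjusted p = 0.0559) and in batch 2 alone (0.635). Of 12 ciliated cell genes, 1 fell over all genes and 0 adjusted over the list alone by limma, with a median of −0.31 and −0.14 and −0.54 by batch (camera adjusted p = 0.0179; adjusted p = 0.568 with an estimated correlation). This call ended without control b2r2 (adjusted p = 0.436, median −0.07) or bleomycin b2r2 (adjusted p = 0.0524), in batch 1 alone (0.534) and with array weights (0.392). Of 12 circadian clock output genes, 2 fell over all genes and 0 adjusted over the list alone by limma, with a median of −0.47 and −0.38 and −1.24 by batch (camera adjusted p = 0.0306; adjusted p = 0.373 with an estimated correlation). The circadian call ended without control b2r1 (adjusted p = 0.0607), control b2r2 (0.137) or bleomycin b2r2 (0.0685), and its median was −0.83 without control b1r1.

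The other 13 lists did not pass by camera. Their medians were −0.12 for alveolar macrophages (adjusted p = 0.102), −0.41 for neutrophils (adjusted p = 0.274), 0.30 for T cells (adjusted p = 0.341), −0.16 for plasma cells and immunoglobulin constant regions (adjusted p = 0.398), 0.28 for complement (adjusted p = 0.260) and −0.05 for alveolar type 1 cells (adjusted p = 0.378). They were −0.11 for club and secretory cells (adjusted p = 0.664), 0.29 for the unfolded protein response (adjusted p = 0.0694), 0.39 for hypoxia and glycolysis (adjusted p = 0.0677), 0.18 for immediate early genes (adjusted p = 0.732) and −0.25 for skeletal muscle (adjusted p = 0.260). The list of P-type pumps and airway ion transport had a median of 0.03 (adjusted p = 0.831) and the sex-linked list 0.01 (adjusted p = 0.784), and in both the median and the camera direction differed in sign. Members of 9 of these lists passed the limma test over all genes. The unfolded protein response had 4 higher and 1 lower (7 and 2 adjusted over the list alone), complement 3 higher and 1 lower (3 and 2 adjusted over the list alone), immediate early genes 3 higher and 1 lower by either adjustment, alveolar macrophages 3 lower and hypoxia 2 higher by either adjustment. Of the alveolar type 1 genes, Col4a4, a chain of basement membrane collagen, rose by 0.53 (adjusted p = 0.0166) and Hopx fell by 0.71 (adjusted p = 0.00885), with 1 higher and 2 lower adjusted over the list alone. By either adjustment 1 gene was higher among the pumps and airway ion transport, Slc26a4, an anion exchanger of airway epithelium, by 1.84 (adjusted p = 0.0113), 1 was higher among club and secretory genes and 1 lower among skeletal muscle genes. In the lists of neutrophils, T cells, plasma cells and sex-linked genes 0 passed by limma by either adjustment.

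The balance of rises and falls moved between fits. With quantile normalization 1747 genes were higher and 1709 lower, with median-ratio scaling 1817 and 1523, with array weights 4198 and 3415, in batch 1 alone 2438 and 2047, and without control b2r2 1906 and 1430. Groups of 4 and 4 did not overlap in 3975 genes, 23.4% of those tested, against 2.86% by chance. The count was 1994 without control b1r2 and 1484, 1715 and 1971 without bleomycin b1r1, b1r2 and b2r2, and it was 1468 without the 3 libraries low in Scgb1a1. Batch 1 alone gave 4485 genes and batch 2 alone gave 29. Both groups held 1 library low in Scgb1a1 and 1 Xist-expressing library. Of the 40 lists tested, 27 passed by camera (15 higher, 12 lower), 17 by fry and 0 by camera with an estimated correlation, where the smallest adjusted p was 0.243 and 3 lists had an unadjusted p under 0.05.

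Ad-ATP12A against Ad-GFP asks what the pump gene added to the injured lung beyond the vector. Atp12a was the 1 gene of 17003 that passed, higher by 3.54 (SE 0.424, adjusted p = 0.0144), with 2.30 in batch 1 and 4.77 in batch 2. All 4 Ad-ATP12A libraries lay above all 4 Ad-GFP libraries (exact permutation p = 0.0286, two-sided, the smallest that 70 relabellings allow). These relabellings ignore batch. As groups, transcripts of T cells, immunoglobulins, interferon responses and dividing cells were higher in Ad-ATP12A lungs and those of cardiac muscle were lower, by camera with its preset correlation alone. The limma adjusted p of Atp12a was 0.0508, 0.0538, 0.107 and 0.104 without each of Ad-GFP b1r1, b1r2, b2r1 and b2r2 and 0.0731 without Ad-ATP12A b2r2, and no gene passed in these fits; 2 genes passed without control b2r2.

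The genes next in rank did not pass. Hamp, which encodes the iron regulator hepcidin, measured 1.10 ± 0.326 against 4.96 ± 1.58 TPM (−1.48, SE 0.301, adjusted p = 0.761). Lck, the proximal kinase of the T cell receptor, measured 21.1 ± 2.35 against 12.8 ± 3.89 TPM (0.72, SE 0.152, adjusted p = 0.965). Sh2d1a, an adaptor of T and NK cells, had a log2 fold change of 0.77 (adjusted p = 0.999), and Cxcr3, a chemokine receptor of activated T cells, of 0.75 (adjusted p = 0.999). At an unadjusted p under 0.05 there were 413 genes, and the groups did not overlap in 131 genes, 0.770% of those tested, against 2.86% by chance.

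All 12 T cell genes had higher means in Ad-ATP12A lungs; none passed over all genes, and 4 passed adjusted over the list alone: Lck, Cd3e (0.64), Cd3g (0.71) and Cd3d (0.63), the last 3 being chains of the T cell receptor complex. The list's median was 0.64, with 0.87 in batch 1 and 0.35 in batch 2 (camera adjusted p = 9.7e-17; adjusted p = 0.200 with an estimated correlation; fry adjusted p = 0.353). The plasma cell and immunoglobulin list had 11 of 12 genes higher, 0 past the limma test over all genes and 1 adjusted over the list alone, Ighg2c, at 358 ± 154 against 38.4 ± 24.2 TPM (3.47), where control libraries held between 9.33 and 246 TPM and those of bleomycin alone between 64.9 and 331 TPM. Igkc, the kappa constant region, measured 3835 ± 2982 against 1184 ± 839 TPM (1.80, adjusted p = 0.999; 1.19 without Ad-GFP b1r2). Their median as a list was 1.32, with 1.39 and 1.17 by batch (camera adjusted p = 3.0e-09; adjusted p = 0.642 with an estimated correlation), and 2.02 without Ad-GFP b1r1, 0.83 without Ad-GFP b1r2 and 0.85 without Ad-ATP12A b2r2. Of 16 genes of the interferon gamma response and MHC class II, 16 had higher means and 0 passed by limma over all genes or adjusted over the list alone, with a median of 0.37 and 0.59 and 0.27 by batch (camera adjusted p = 1.1e-06; adjusted p = 0.642 with an estimated correlation). That median was 0.17 without Ad-GFP b2r1 and 0.25 without Ad-ATP12A b2r1. Of 17 cell cycle genes, 16 had higher means and 0 passed by limma by either adjustment, with a median of 0.39 and 0.11 and 0.67 by batch (camera adjusted p = 5.7e-10; adjusted p = 0.642 with an estimated correlation). All 10 cardiac muscle genes had lower means, such as Tnnt2, a troponin, at 37.7 ± 17.6 against 83.2 ± 47.8 TPM (−1.05, adjusted p = 0.999; −0.67 without Ad-GFP b1r1), with a median of −0.92 and −1.28 and −0.69 by batch (camera adjusted p = 1.5e-05; adjusted p = 0.642 with an estimated correlation). The cardiac median was −0.56 without Ad-GFP b1r1 and −1.41 without Ad-GFP b2r2. In one batch alone 3 of these 5 lists lost their camera calls, cell cycle in batch 1 (adjusted p = 0.396) and interferon gamma (adjusted p = 0.369) and cardiac muscle (adjusted p = 0.103) in batch 2.

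The other 10 lists that passed by camera lost their calls without 1 or more libraries, and their adjusted p with an estimated correlation lay between 0.642 and 0.778. After each list's median, batch medians and camera adjusted p stand the range of the median and the highest adjusted p over fits without 1 library, and the libraries that ended the call or moved the median by over 1.5 times. Type I interferon genes had a median of 0.32, with 0.68 and −0.03 by batch (9.2e-07; 0.12 to 0.54, adjusted p up to 0.0834, without Ad-GFP b1r2, b2r1 or b2r2 or Ad-ATP12A b1r1), and cytokines and chemokines 0.27, with 0.06 and 0.67 (3.8e-04; 0.06 to 0.46, up to 0.162, Ad-GFP b1r2, b2r1 or b2r2 or Ad-ATP12A b1r2). Alveolar type 1 genes had −0.21, with −0.03 and −0.40 (0.00906; −0.27 to −0.06, up to 0.543, Ad-GFP b2r1 or Ad-ATP12A b2r1). Monocytes and interstitial macrophages had 0.46, with 0.24 and 0.74 (0.00763; 0.13 to 0.83, up to 0.331, Ad-GFP b1r1, b2r1 or b2r2 or Ad-ATP12A b1r2 or b2r1), and B cells 0.38, with 1.02 and −0.42 (0.00930; 0.07 to 0.53, up to 0.885, Ad-GFP b1r2 or Ad-ATP12A b1r1 or b1r2). Neutrophils had 0.26, with −0.08 and 0.74 (0.0275; 0.15 to 0.43, up to 0.286, Ad-GFP b1r2 or b2r1 or Ad-ATP12A b1r1, b2r1 or b2r2), and complement 0.10, with 0.03 and 0.23 (0.0304; 0.04 to 0.23, up to 0.604, any Ad-GFP library or Ad-ATP12A b1r1, b2r1 or b2r2). Myofibroblast genes had 0.23, with −0.25 and 0.71 (0.0464; 0.0037 to 0.39, up to 0.887, control b1r2, b2r1 or b2r2, bleomycin b2r2, Ad-GFP b1r1, b2r1 or b2r2, or Ad-ATP12A b1r1, b2r1 or b2r2). Hypoxia and glycolysis genes had 0.19, with −0.12 and 0.50 (0.0457; 0.05 to 0.35, up to 0.673, control b2r1 or b2r2, bleomycin b2r2, Ad-GFP b1r1, b2r1 or b2r2, or Ad-ATP12A b1r2, b2r1 or b2r2). Club and secretory genes had 0.31, with 0.63 and −0.06 (0.0457; 0.17 to 0.69, up to 0.414, control b1r2 or b2r2, any Ad-GFP library, or Ad-ATP12A b1r1, b1r2 or b2r1). No member of these lists passed over all genes by limma, and adjusted over the list alone 1 did, Ccl4, a chemokine (0.87).

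The collagens did not pass: 14 of 15 had higher means in Ad-ATP12A lungs, and their median was 0.19, with −0.23 in batch 1 and 0.68 in batch 2 (camera adjusted p = 0.06), a difference between batches that passed (camera adjusted p = 1.0e-05). Against bleomycin the collagen median was −0.04 in Ad-ATP12A lungs, with −1.07 and 0.78 by batch (difference adjusted p = 2.2e-07). Col1a1 measured 571 ± 467 against 424 ± 299 TPM (0.36, adjusted p = 0.999). The collagen list score, the mean centred log2(TPM + 1) of its genes, ran from −0.23 to 1.38 in the Ad-ATP12A libraries and from −0.62 to 1.05 in the Ad-GFP libraries. Within a batch the Ad-GFP libraries also lay apart, with −0.62 and 0.68 in batch 1 and 0.02 and 1.05 in batch 2. Across genes, which are not independent replicates, the fold changes of Ad-ATP12A against Ad-GFP and of bleomycin against control correlated with Pearson r = 0.20 (exact p = 0.657) and Spearman rho = 0.334 (exact p = 0.457), over 70 relabellings of the vector libraries. Pearson r was 0.04, 0.35, 0.02 and 0.31 without Ad-GFP b1r1, b1r2, b2r1 and b2r2, and 0.33, 0.09 and 0.13 without Ad-ATP12A b1r2, b2r1 and b2r2. In 5 of the 40 lists, of NK cells, ciliated cells, P-type pumps, vacuolar pump and lysosome, and adipocytes, the median, mean and camera direction differed in sign, and none of these passed.

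**Figure D3:**
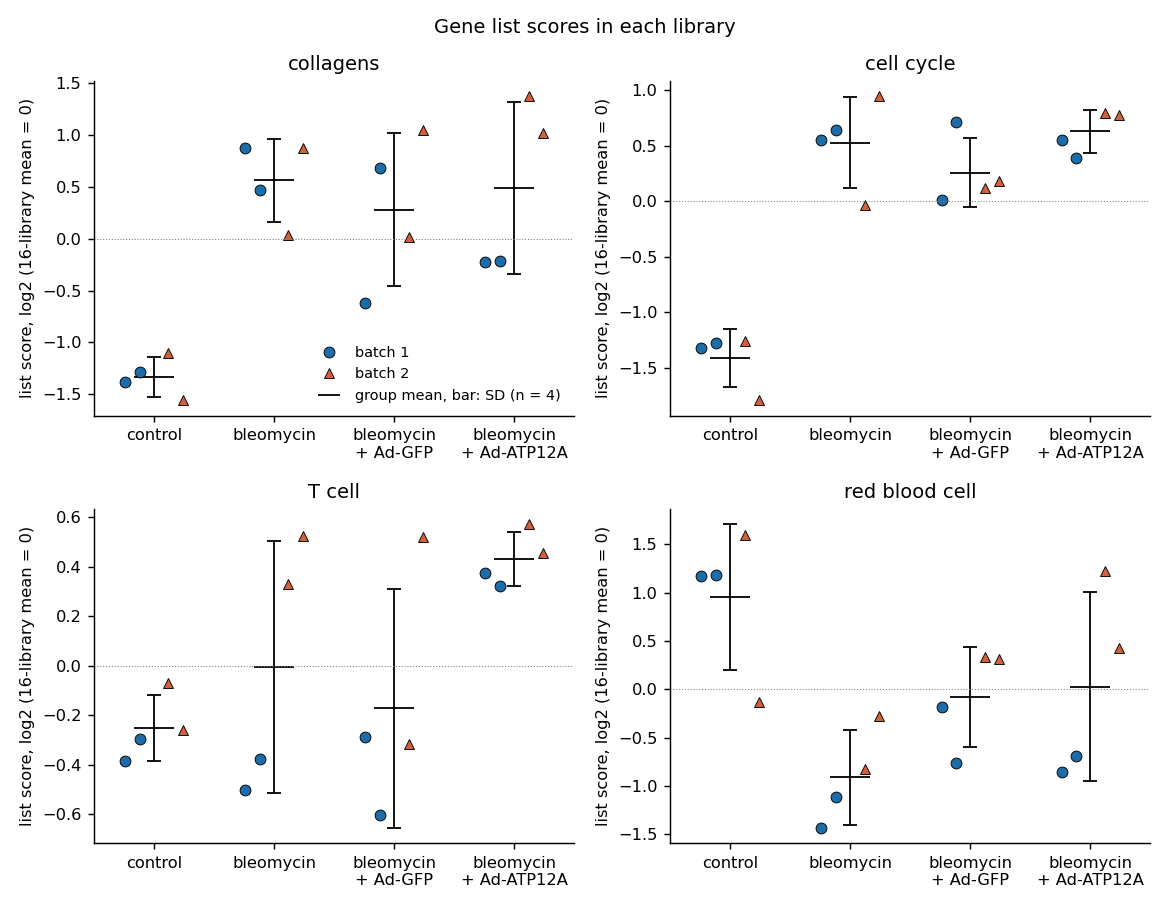
List scores per library, the mean centred log2(TPM + 1) of each list's genes, in the 4 groups for collagens, cell cycle, T cell and red blood cell genes, with points marked by batch and bars for the group mean ± SD. T cell scores of the Ad-ATP12A libraries lie between 0.32 and 0.57 and those of the Ad-GFP libraries between −0.60 and 0.52.

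By camera 15 lists passed, 13 higher and 2 lower; 9 of these 15 had the same sign in both batches. By fry 0 lists passed (1 at an unadjusted p under 0.05) and with an estimated correlation 0 (2 unadjusted), where the smallest adjusted p was 0.200. The count of lists was 7 without Ad-GFP b2r1 and 25 without Ad-ATP12A b1r2. Ad-ATP12A held 3 of the 4 Xist-expressing libraries of these groups, and Ad-GFP held the 1 library low in Scgb1a1. With Xist-expressing libraries as a term, Atp12a had an adjusted p of 0.0546, and without the 3 libraries low in Scgb1a1 0.107. The Xist term also ended the calls of neutrophils (adjusted p = 0.184), B cells (0.457), complement (0.0953) and club cells (0.517).

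Ad-GFP against bleomycin asks what the control vector itself did. The genes that passed were 2 of 17003. Kng1 (ENSMUSG00000022875), a kininogen gene whose product is a precursor of bradykinin, rose from 0.468 ± 0.0950 to 10.3 ± 4.56 TPM (2.84, SE 0.333, adjusted p = 0.0113), by 3.15 and 2.52 in the batches. Asgr2 (ENSMUSG00000040963), a subunit of the asialoglycoprotein receptor, fell from 6.59 ± 2.55 to 1.19 ± 0.436 TPM (−1.74, SE 0.234, adjusted p = 0.0269), with −1.92 and −1.56 in the batches. Atp12a did not pass (−0.04, SE 0.424, adjusted p = 1.00; exact permutation p = 0.886, two-sided). In control lungs Kng1 measured 0.015 ± 0.0191 TPM and Asgr2 0.505 ± 0.198 TPM. Kng1 shares sequence with its paralog Kng2, so part of its reads are assigned by estimate.

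Both calls depended on single libraries. The adjusted p of Kng1 was 0.0699 and 0.0679 without bleomycin b1r1 and b1r2, and 0.0754, 0.0630 and 0.0868 without Ad-GFP b1r1, b1r2 and b2r1. That of Asgr2 lay between 0.0602 and 0.193 without control b1r1 or b2r1, bleomycin b1r1, b1r2 or b2r2, or any of the 4 Ad-GFP libraries. Next in rank and not passing were Hpse, which encodes heparanase (0.87, adjusted p = 0.733), Chia1, an acidic chitinase (106 ± 54.5 against 28.0 ± 4.17 TPM, 1.72, adjusted p = 1.00), and Fgf13 (−0.70, adjusted p = 1.00). At an unadjusted p under 0.05 there were 287 genes, and the groups did not overlap in 137 genes, 0.806% of those tested, against 2.86% by chance.

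**Figure D4:**
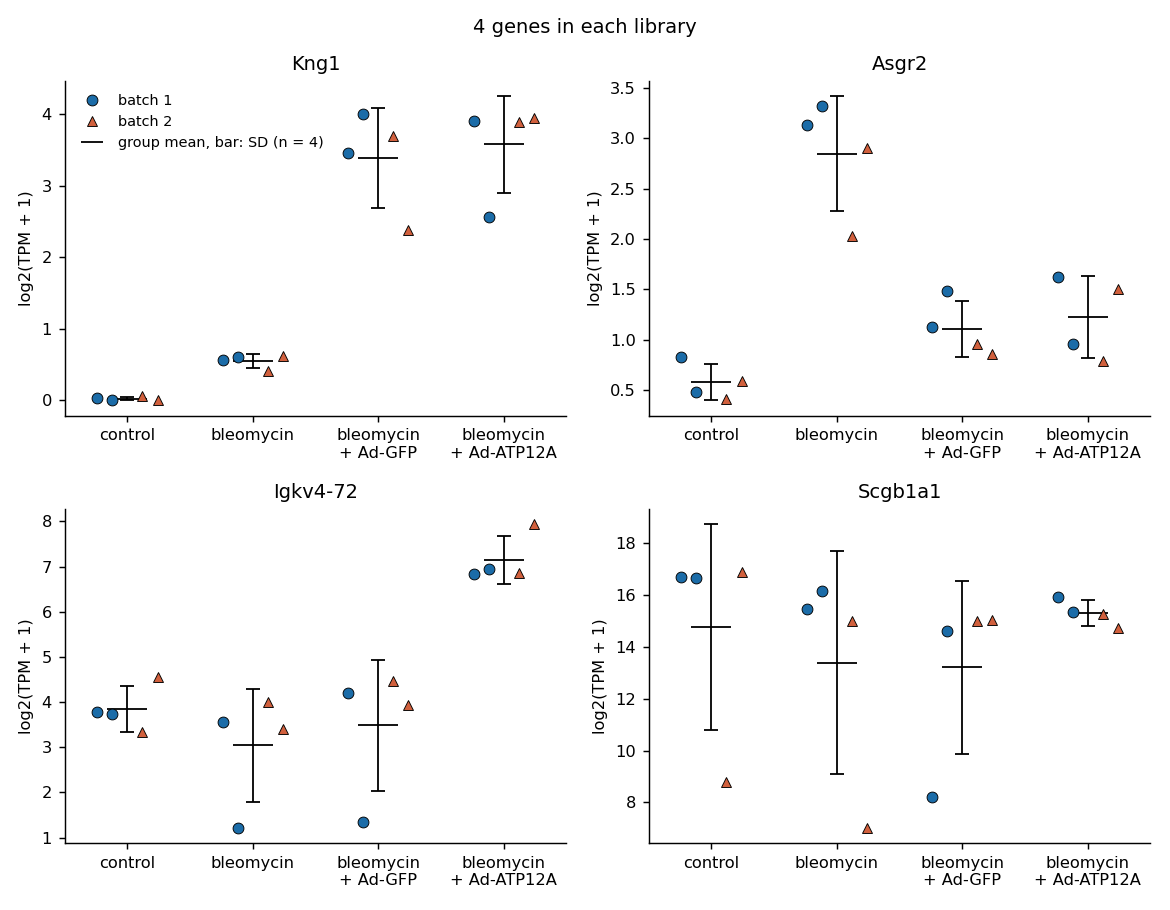
Kng1, Asgr2, Igkv4-72 and Scgb1a1 per library, as log2(TPM + 1), in the 4 groups, with points marked by batch and bars for the group mean ± SD. Kng1 lies between 4.23 and 15.08 TPM in the 8 vector libraries and between 0.33 and 0.54 TPM in the 4 libraries of bleomycin alone.

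Among lists, 15 passed by camera, 7 higher and 8 lower in Ad-GFP lungs, and 11 had the same sign in both batches. By fry 0 passed (0 at an unadjusted p under 0.05) and with an estimated correlation 0 (4 unadjusted), where the smallest adjusted p was 0.435. No member of these 15 lists passed by limma over all genes or adjusted over the list alone; in the plasma cell list, which did not pass, 1 did adjusted over the list alone, the IgG heavy chain Ighg1 (4.04, adjusted p over all genes = 1.00). All 6 red blood cell genes had higher means in Ad-GFP lungs, such as Hba-a1 at 1605 ± 475 against 847 ± 262 TPM (0.92, adjusted p = 1.00), with a median of 0.91 and 0.89 in either batch (camera adjusted p = 3.4e-08; adjusted p = 0.435 with an estimated correlation). This was the 1 list of the 15 whose call stood without any single library. All 17 cell cycle genes had lower means, with a median of −0.27 and −0.19 and −0.27 by batch (camera adjusted p = 1.3e-04; adjusted p = 0.772 with an estimated correlation; camera adjusted p = 0.105 without bleomycin b2r2). The cell cycle median was −0.51 without bleomycin b2r1, −0.10 without bleomycin b2r2, −0.17 without Ad-GFP b1r1 and −0.45 without Ad-GFP b1r2.

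The calls of the remaining 13 lists ended without 1 or more libraries, and with an estimated correlation their adjusted p lay between 0.435 and 0.822; values are in the order used for the lists of Ad-ATP12A against Ad-GFP. B cell genes had a median of −0.55, with −0.02 and −1.08 by batch (camera adjusted p = 4.3e-04; −0.78 to −0.35, adjusted p up to 0.0691, without bleomycin b2r1 or Ad-GFP b1r2), and neutrophil genes −0.40, with −0.01 and −0.80 (0.00236; −0.63 to −0.23, up to 0.160, bleomycin b1r2 or b2r1 or Ad-GFP b2r1). Club and secretory genes had 0.43, with 1.25 and −0.06 (0.00143; 0.30 to 0.75, up to 0.0669, Ad-GFP b1r1 or b2r2), and mesothelial genes 0.15, with 0.14 and 0.16 (0.00387; 0.08 to 0.21, up to 0.0656, bleomycin b1r1 or b2r1 or Ad-GFP b1r1 or b2r1). Cardiac muscle genes had 0.50, with 1.72 and −0.51 (0.00137; 0.12 to 1.02, up to 0.189, bleomycin b1r1, b1r2 or b2r1 or Ad-GFP b1r1, b2r1 or b2r2), and skeletal muscle genes 0.40, with 0.65 and −0.10 (0.0215; 0.21 to 0.59, up to 0.0963, bleomycin b1r2 or Ad-GFP b1r1 or b1r2). The interferon gamma list had 0.25, with 0.18 and 0.19 (0.00597; −0.04 to 0.39, up to 0.759, bleomycin b1r2 or b2r1 or Ad-GFP b2r1 or b2r2). Scar macrophage genes had 0.12, with −0.05 and 0.42 (0.0237; −0.12 to 0.30, up to 0.815, bleomycin b1r1 or b2r1 or any Ad-GFP library), and alveolar macrophage genes −0.47, with −0.19 and −0.74 (0.0267; −0.72 to −0.18, up to 0.364, bleomycin b1r1, b1r2 or b2r1 or Ad-GFP b1r2 or b2r2). Proteases had −0.44, with −0.51 and −0.13 (0.0356; −0.64 to −0.15, up to 0.870, control b2r2, bleomycin b1r1 or b1r2, or Ad-GFP b1r1 or b2r1), and T cells −0.16, with −0.04 and −0.45 (0.0448; −0.29 to −0.07, up to 0.919, control b2r2, bleomycin b1r1, b2r1 or b2r2, or Ad-GFP b1r2, b2r1 or b2r2). Cytokines had −0.21, with −0.23 and −0.18 (0.0448; −0.40 to −0.05, up to 0.993, control b2r2, any bleomycin or Ad-GFP library, or Ad-ATP12A b1r1) and immediate early genes −0.16, with −0.16 and −0.42 (0.0448; −0.28 to −0.06, up to 0.532, control b2r2, any bleomycin library, Ad-GFP b1r1, b2r1 or b2r2, or Ad-ATP12A b1r1). In 3 of the 40 lists, of complement, aerocytes and hypoxia, the median, mean and camera direction differed in sign, and none of these passed.

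The gene count was 1 without control b1r1, control b2r1 or Ad-GFP b2r2, and 0 without bleomycin b1r1 or b1r2 or Ad-GFP b1r1, b1r2 or b2r1. Each group held 1 library low in Scgb1a1 and 1 Xist-expressing library. Without the 3 libraries low in Scgb1a1, 0 genes passed by limma and 9 lists by camera, and the medians of cell cycle genes, proteases and cytokines turned to 0.06, 0.05 and 0.02.

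Ad-ATP12A against bleomycin asks what the vector and the pump gene did together, and it shares the 4 bleomycin libraries with the comparison of Ad-GFP. In all, 4 of 17003 genes passed. Atp12a rose by 3.49 (SE 0.424, adjusted p = 0.00837), by 2.29 and 4.69 in the batches (exact permutation p = 0.0286, two-sided, the smallest possible). Kng1 rose from 0.468 ± 0.0950 to 11.8 ± 4.59 TPM (3.03, SE 0.333, adjusted p = 0.00518), by 2.65 and 3.40 in the batches, and Asgr2 fell to 1.40 ± 0.664 TPM (−1.63, SE 0.234, adjusted p = 0.0290). Igkv4-72, an immunoglobulin kappa variable segment named only after its values were seen, rose from 9.20 ± 5.76 to 149 ± 64.2 TPM (4.10, SE 0.591, adjusted p = 0.0290), and control lungs held 14.2 ± 5.82 TPM of it.

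The calls of Atp12a and Kng1 stood without any single library. That of Asgr2 ended (adjusted p between 0.0523 and 0.199) without any one of 13 libraries, which were all but control b1r1, bleomycin b2r1 and Ad-ATP12A b2r2. That of Igkv4-72 ended (adjusted p between 0.0558 and 0.170) without control b1r2 or b2r2, bleomycin b1r2, b2r1 or b2r2, Ad-GFP b2r1 or b2r2, or Ad-ATP12A b1r1, b1r2 or b2r2. Next in rank were Ighg1, an IgG heavy chain, at 1385 ± 1308 against 77.3 ± 148 TPM (6.36, SE 1.13, adjusted p = 0.208; 0.00532 to 0.0335 without bleomycin b2r1 or Ad-ATP12A b2r1), and Slpi, a secreted antiprotease, at 161 ± 89.6 against 51.9 ± 21.1 TPM (1.55, adjusted p = 0.529). At an unadjusted p under 0.05 there were 509 genes, and the groups did not overlap in 219 genes, 1.29% of those tested, against 2.86% by chance. The gene count was 2 without control b1r2 or b2r2, bleomycin b1r2, Ad-GFP b2r1 or b2r2, or Ad-ATP12A b1r1 or b1r2, and 6 at most.

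By camera 10 lists passed, 9 higher and 1 lower, of which 7 had the same sign in both batches. Of 16 interferon gamma and MHC class II genes, 12 had higher means and 6 passed adjusted over the list alone, none over all genes by limma, among them Gbp2 and Gbp5, which encode interferon-induced GTPases (0.94 and 1.05), and Ido1, a tryptophan-degrading enzyme (0.75). The 4 genes with lower means were MHC class II chains and Cd74, their invariant chain. The list's median was 0.62, with 0.67 and 0.54 by batch (camera adjusted p = 9.8e-13; adjusted p = 0.210 with an estimated correlation). All 12 T cell genes had higher means, 1 of them past adjusted over the list alone (Lck, 0.55), with a median of 0.43 and 0.81 and −0.11 by batch (camera adjusted p = 8.6e-12; adjusted p = 0.210 with an estimated correlation). All 6 red blood cell genes had higher means, with a median of 1.00 and 0.59 and 1.42 by batch (camera adjusted p = 2.4e-09; adjusted p = 0.210 with an estimated correlation). Plasma cell and immunoglobulin genes had 11 of 12 higher, 1 past adjusted over the list alone (Ighg1), with a median of 0.93 and 1.51 and 0.41 by batch (camera adjusted p = 3.5e-08; adjusted p = 0.446 with an estimated correlation). Their median was 1.41 without Ad-ATP12A b2r1 and 0.33 without Ad-ATP12A b2r2, and the call ended with Xist-expressing libraries as a term (adjusted p = 0.0802). Of 11 club and secretory genes, 8 had higher means and 4 passed adjusted over the list alone: the secretoglobin Scgb3a1, at 519 ± 266 against 196 ± 36.8 TPM (1.27), the antimicrobial lectin Reg3g (1.60), which has close paralogs, and the mucins Muc5b (1.08) and Muc5ac (1.38). Their median was 1.08, with 1.70 and 0.08 by batch (camera adjusted p = 4.5e-07; adjusted p = 0.210 with an estimated correlation), and 0.62 without bleomycin b1r2. In batch 2 alone the camera calls of T cells (adjusted p = 0.332), plasma cells (adjusted p = 0.0934) and club cells (adjusted p = 0.333) ended.

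The other 5 lists lost their calls without 1 or more libraries, and values are in the same order, with the adjusted p of an estimated correlation last. Type I interferon genes had a median of 0.23, with 0.40 and 0.15 by batch (camera adjusted p = 2.3e-06; −0.03 to 0.36, adjusted p up to 0.147, without bleomycin b2r1 or Ad-ATP12A b1r1 or b2r2; adjusted p = 0.695 with an estimated correlation). Hypoxia genes had 0.18, with −0.29 and 0.70 (0.00124; −0.02 to 0.33, up to 0.221, bleomycin b1r1 or b2r1 or Ad-ATP12A b1r2, b2r1 or b2r2; adjusted p = 0.695). Complement genes had 0.08, with 0.02 and 0.34 (0.0175; 0.04 to 0.17, up to 0.249, bleomycin b1r1 or b2r1 or Ad-ATP12A b1r1, b1r2 or b2r2; adjusted p = 0.695). Cell cycle genes had 0.11, with −0.15 and 0.40 (0.0175; −0.09 to 0.29, up to 0.594, bleomycin b1r2, b2r1 or b2r2 or any Ad-ATP12A library; adjusted p = 0.903). Capillary genes had −0.27, with −0.02 and −0.49 (0.0408; −0.49 to −0.12, up to 0.748, bleomycin b2r1, Ad-GFP b1r2 or Ad-ATP12A b1r1, b1r2 or b2r1; adjusted p = 0.903). The list count was 19 without bleomycin b1r1, 16 without bleomycin b2r1 and 18 without Ad-ATP12A b1r2; by fry 0 lists passed (1 at an unadjusted p under 0.05), and with an estimated correlation 0 (4 unadjusted), where the smallest adjusted p was 0.210. In 8 of the 40 lists, which were collagens, NK cells, cytokines, transitional epithelium, mesothelium, unfolded protein response, P-type pumps and circadian output, the median, mean and camera direction differed in sign, and none of these passed. In the NK list 1 gene passed adjusted over the list alone, Nkg7, a granule protein (0.73). Bleomycin held 1 Xist-expressing library and Ad-ATP12A 3, and without the 3 libraries low in Scgb1a1 no gene passed by limma.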

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

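The tests of Scgb1a1 and Kng1 were chosen only after the result was seen, as was the fit with Xist-expressing libraries as a term; the other tests of the T cell list were set before.

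A library was named here when it stood apart from the other 3 of its group, by a gap to the nearest that was a larger share of the group's range than Dixon's 95% limit for 4 samples; chance alone names about 1 group in 20. Of 277 group-and-gene values 13 were past it, and of 102 list scores 5. Bleomycin b2r1 stood apart in 4: Atp12a at 0.20 TPM against 0 to 0.01 (ratio 0.945), Cxcl10 at 13.9 against 35.1 to 42.1 TPM (0.834), Ear1, which shares reads with Ear2, at 31.7 against 14.8 to 15.6 TPM (0.928), and Aurka at 5.17 against 10.2 to 10.6 TPM (0.942). Control b2r2 stood apart in Col3a1 at 55.3 against 99.4 to 109.6 TPM (0.856), in Etv5 at 45.4 against 79.9 to 87.6 TPM (0.859), and in the scores of matrix proteases, −1.40 against −1.11 to −1.06 (0.86), and cell cycle, −1.80 against −1.33 to −1.26 (0.871). Control b2r1 stood apart in Wnt2 at 15.3 against 12.5 to 12.7 TPM (0.938), and control b1r1 in Tppp3 at 390.1 against 432 to 441 TPM (0.832) and in the adipocyte score, 1.68 against 0.54 to 0.61 (0.936). Bleomycin b1r2 stood apart in Cr2 at 3.09 against 6.09 to 6.66 TPM (0.877). Ad-GFP b1r2 stood apart in Igkv4-72 at 1.53 against 14.3 to 21.2 TPM (0.83) and in the B cell score, −1.09 against −0.35 to −0.27 (0.9). Ad-GFP b2r2 stood apart in Gbp2 at 130.3 against 48.5 to 51.5 TPM (0.942) and in the interferon gamma score, 1.05 against −0.24 to −0.06 (0.858). Among Ad-ATP12A libraries, b2r2 stood apart in Igkv4-72 at 245 against 114 to 122 TPM (0.906) and b1r2 in Kng1 at 4.93 against 13.9 to 14.4 TPM (0.967).

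Effects that differed between batches were the other reason. In bleomycin against control 11 genes differed by the interaction test (3230 at an unadjusted p under 0.05), 8 of them with an established symbol: AI197445 (−2.71), Mob1b (−1.48), Clock (−1.51), Ahcyl2 (−2.09), Lnpep (−1.20), Fam124b (−2.80), Usp2 (1.98) and Med13 (−1.19), each the log2 fold change of batch 1 minus that of batch 2. By camera 14 lists differed between batches in this comparison, 21 in Ad-ATP12A against Ad-GFP, 21 in Ad-GFP against bleomycin and 23 in Ad-ATP12A against bleomycin. The rise of Atp12a was smaller in batch 1 by −2.47 against Ad-GFP (limma adjusted p = 0.102) and by −2.40 against bleomycin (adjusted p = 0.0594), so neither difference passed over all genes. In the vector comparisons 0 genes passed by limma, with 1070, 538 and 3368 at an unadjusted p under 0.05 in the order just given.

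The log2 difference of Scgb1a1 from the rest of its group was −7.96 in control b2r1, −8.51 in bleomycin b2r2 and −6.66 in Ad-GFP b1r1. A loss of airway secretory cells from the lung piece is argued against, since the other club and secretory genes were higher in those libraries, by a median of at least 0.41, with Scgb3a2 at 4009 to 11745 TPM against 866 to 3416 TPM in the other 13, while Cyp2f2, at 816 to 2972 against 383 to 2404 TPM, overlapped. A scaling of the whole library is argued against too, as the median gene moved by at most 0.15. What stays open is a property of the animals that carry this gene, or of its reads or their mapping, which may be unequal between libraries and which the table cannot settle. Beyond the loss of secretory cells, no biological explanation was tested.

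The T cell list was higher in Ad-ATP12A than in Ad-GFP lungs, by a median of 0.64. Unequal sex as the whole cause is argued against, as the median was 0.54 with the Xist term (camera adjusted p = 1.1e-08). A single batch stays open: the batches differed (camera adjusted p = 0.0343), with a median of 0.35 in batch 2. Scores there were 0.57 and 0.46 in Ad-ATP12A, and −0.32 and 0.52 in Ad-GFP, so the gap rested on Ad-GFP b2r1. Chance stays open too: 3 of the 35 splits of the 8 libraries gave a median as large in size (highest other 0.66). An effect of the pump gene on T cells is only a hypothesis beside chance, unequal sex and batch.

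Kng1 was higher in both vector groups than in bleomycin alone. Liver RNA is argued against, since Alb, the most abundant liver transcript, was lower in the vector libraries by −0.175 TPM and reached 0.50 TPM at most. Reads moved from an unchanged Kng2 are argued against, as its sum with Kng1 was higher in every vector library, by at least 5.49 TPM. Kng2 was higher there too (4.48 to 10.24 against 1.29 to 3.38 TPM in bleomycin alone), so its reads assigned to Kng1 stay open. An effect of the adenovirus on Kng1 is a hypothesis beside it. The groups' handling may differ too, which the labels omit and was not tested.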

How the results depend on the processing

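The fits with Xist-expressing libraries as a term and without the 3 libraries low in Scgb1a1 were tests chosen only after the result was seen. Over 29 alternatives a comparison, Atp12a turned direction in 6 for bleomycin against control and 5 for Ad-GFP against bleomycin, where it never passed, and lost its call in 11 for Ad-ATP12A against Ad-GFP and 3 against bleomycin. The other named genes gave 4388 values over all alternatives and comparisons, of which 4096 kept direction and side of the threshold, 256 lost a call, 27 gained one and 9 turned direction. Called lists gave 2007, of which 1763 kept both, 230 lost the call and 14 turned by camera's direction; 11 further medians crossed 0 while that direction stayed. For each value below the cause was not tested, except where fewer libraries or more genes tested are part of the alternative. The deposited scale already has a pseudocount of 1, so the alternative with values as deposited is identical and was not run. Read depth is unknown, so what depth limits cannot be given.

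In bleomycin against control the gene count was 7613 with array weights, 29 in batch 2 alone, 1468 without the 3 libraries low in Scgb1a1, 934 with an absolute log2 fold change of at least 1, and 1484 to 3701 leaving out 1 library. The list count was 0 with an estimated correlation, 17 by fry, and 24 to 28 leaving out 1 library. Atp12a, never past the threshold (adjusted p 0.836 to 1.00), was −0.0823 with quantile normalization, −0.0831 with array weights, and −0.10 to 0.18 leaving out 1 library. The alveolar type 2 median was 0.20 in batch 2 alone.

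In Ad-ATP12A against Ad-GFP the gene count was 0 by limma without a filter, with the stricter filter, which removed Atp12a, in the 8 libraries alone, with the replicate block, in batch 1 alone, with the Xist term and without the libraries low in Scgb1a1, and 0 to 2 leaving out 1 library, against 413 at an unadjusted p under 0.05 in the reported fit. The list count was 0 with an estimated correlation, 0 by fry, and 7 to 25 leaving out 1 library. Atp12a lost its call at 3.54 without a filter (adjusted p 0.0758), in the 8 libraries alone (0.481) and with the replicate block (0.0834), at 2.30 in batch 1 alone (0.182), at 3.63 with the Xist term (0.0546) and at 3.68 without the libraries low in Scgb1a1 (0.107), and was 3.17 to 3.99 leaving out 1 library, with adjusted p over all alternatives of 4.4e-04 to 0.481. Directions turned for Cd79a in batch 2 (−0.17), for Col5a2 in batch 1 (−0.22), without the libraries low in Scgb1a1 (−0.0376) and leaving out 1 library (−0.0278 to 0.704, the lowest without Ad-GFP b1r1), and for the list medians of myofibroblasts (−0.25), neutrophils (−0.0772) and hypoxia (−0.12) in batch 1 and of B cells in batch 2 (−0.42). In batch 2 the medians of type I interferon (−0.0266; adjusted p 0.788) and club and secretory genes (−0.0640; 0.306) also crossed 0, with camera's direction kept.

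In Ad-GFP against bleomycin the gene count was 1 with a pseudocount of 0.1, the stricter filter, quantile normalization, median-ratio scaling, no batch term or the 8 libraries alone, where Kng1 (adjusted p 0.114) and Asgr2 (0.187) both lost their calls and the 1 gene was another; it was 0 by limma without a filter, in either batch alone and without the libraries low in Scgb1a1, against 287 at an unadjusted p under 0.05; and 0 to 3 leaving out 1 library. The list count was 8 without a filter, 9 without the libraries low in Scgb1a1, 0 with an estimated correlation, 0 by fry, and 11 to 21 leaving out 1 library. Atp12a was 0.0337 with quantile normalization and −0.195 to 0.0794 leaving out 1 library. In batch 2 alone Scgb3a1 (−0.0571), Reg3g (−0.0231), Myh6 (−0.54), Tnnt2 (−0.47) and the cardiac median (−0.51) turned, as did the camera direction of proteases (median −0.13). Without the libraries low in Scgb1a1 the medians of proteases (0.0502) and cell cycle (0.0613) turned, and leaving out 1 library the interferon gamma median ran from −0.0357 to 0.389. Medians that crossed 0 with camera's direction kept were those of club (−0.0571) and skeletal muscle (−0.10) in batch 2, of scar macrophages in batch 1 (−0.0462) and without bleomycin b2r1 (−0.118) or Ad-GFP b2r2 (−0.0438), and of cytokines without the libraries low in Scgb1a1 (0.0200).

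In Ad-ATP12A against bleomycin the gene count was 2 with a pseudocount of 0.1, the stricter filter, no batch term or the Xist term, 1 in batch 2 alone, 0 by limma in the 8 libraries alone and without the libraries low in Scgb1a1, against 509 at an unadjusted p under 0.05, and 2 to 6 leaving out 1 library. The list count was 26 in batch 1 alone, 19 in batch 2 alone, 22 with the Xist term, 0 with an estimated correlation, 0 by fry, and 9 to 19 leaving out 1 library. Atp12a lost its call at 3.49 in the 8 libraries alone (adjusted p 0.235), at 2.29 in batch 1 alone (0.0823) and at 3.32 without the libraries low in Scgb1a1 (0.110), and was 3.13 to 3.94 leaving out 1 library, with adjusted p over all alternatives of 4.3e-04 to 0.235. In batch 1 alone Kdr (0.0819) and the medians of cell cycle (−0.15) and hypoxia (−0.29) turned, as did the camera direction of complement (median 0.0193), and leaving out 1 library the cell cycle median ran from −0.0939 to 0.290. The T cell median crossed 0 in batch 2 (−0.108; adjusted p 0.332), as did those of type I interferon without Ad-ATP12A b1r1 (−0.0319) and hypoxia without bleomycin b2r1 (−0.0187), with camera's direction kept. The correlation of the fold changes of Ad-ATP12A against Ad-GFP with those of bleomycin against control ran from 0.0156 to 0.349 leaving out 1 library.

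Genes whose effect differed between batches numbered 33 without a filter, 153 with the stricter filter, 170 with quantile normalization and 235 with median-ratio scaling in bleomycin against control. They numbered 17, 21 and 22 without a filter in the vector comparisons in the order above, and 8 with the stricter filter in Ad-ATP12A against bleomycin. Equal replicate numbers in a batch did not pair the libraries: of 12 pairs 1 had a residual correlation over 0.1, and the range was −0.158 to 0.212. With batch and replicate number as a block, the gene counts in the order above were 2636, 0, 2 and 4.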

Other observations

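The tests of collagens against Xist and of Igkv4-72 were chosen only after the result was seen, and the genes named beside the batches were too, as was the count of splits besides Atp12a; the other counts of splits were set before.

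In the fit over all groups 3141 genes differed between the batches, 2783 higher and 358 lower in batch 2; the labels do not say what a batch is, and what set these genes apart was not tested. By camera 6 lists differed. Of 12 ciliated cell genes, 8 were lower in batch 2 (median −0.56, camera adjusted p = 8.4e-07), and lower too were the lists of club and secretory cells (−0.61, adjusted p = 0.00103), transitional epithelium (−0.28, adjusted p = 0.00875) and alveolar type 2 cells (−0.22, adjusted p = 0.0154). Those of complement (0.44, adjusted p = 0.0154) and T cells (0.38, adjusted p = 0.0275) were higher. Retnla, the product of alternatively activated macrophages that rose with bleomycin, was lower by −1.57 in batch 2 (limma adjusted p = 0.0226), and Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was higher by 1.82 (adjusted p = 0.00677).

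Among lungs given bleomycin, the collagen list was lower in libraries that express Xist. The difference of the list score, Xist-expressing minus others within a treatment group, was −0.71 in bleomycin, −1.20 in Ad-GFP and −1.18 in Ad-ATP12A lungs, with a mean of −1.03. An exact two-sided permutation within groups gave p = 0.0156, the smallest that 64 relabellings allow, but it ignores batch, and in Ad-ATP12A lungs both batch 1 libraries express Xist, so that difference mixes batch with Xist. Within group and batch the difference was −0.84 in bleomycin (batch 2), −1.30 in Ad-GFP (batch 1) and −0.36 in Ad-ATP12A lungs (batch 2), each between single libraries, and the exact two-sided permutation p was 0.25, the smallest that 8 relabellings allow. A weaker fibrotic response in female mice may be considered only as a hypothesis that these libraries are too few to decide; the labels give no sex, and the pattern was noticed in these data first.

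In Ad-ATP12A against Ad-GFP the log2 fold change of Igkv4-72 was 3.66 (limma adjusted p = 0.198; 0.0677 to 0.843 over alternatives) and that of Igkc, the constant region shared by kappa chains, 1.80 (adjusted p = 0.999; 1.19 without Ad-GFP b1r2), so neither passed, and they differed by 1.86 (SE 0.371). The segment held between 2.09% and 6.67% of the TPM of 81 kappa variable segments in Ad-ATP12A libraries and at most 1.89% in the others. The segment was picked for its rise, and in 10 of 35 splits of the 8 libraries the segment that differed most from Igkc, by the difference over its SE, did so by as much (5.01 in the real split, 16.2 in the highest other). More B lineage cells in general therefore stays open beside an antibody response that favours the segment, which may be considered as a hypothesis; reads shared between similar segments were not tested.

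Other splits of the 8 libraries were compared with the real one. The splits ignored batch, while each real group held 2 libraries of each batch. Splits that keep this balance are fewer than 35, and their share was not computed. For bleomycin against control the real split gave 3201 genes and the highest of the other splits 1, so 1 of 35 splits gave as many, which argues against chance. For Ad-ATP12A against bleomycin the real split gave 4 genes, or 3 besides Atp12a, the gene the vector is named for. The highest other gave 1 in the fit of all 16 libraries (1 of 35, the fewest possible). Chance cannot be excluded for so small a count, since the splits ignored batch. That count was 0 by limma in the 8 libraries alone and without the 3 libraries low in Scgb1a1, against 509 at an unadjusted p under 0.05 in the reported fit. For Ad-ATP12A against Ad-GFP 8 of 35 splits gave as many genes as the real 1, so chance cannot be excluded for the count; the highest other gave 2060. That split set Ad-GFP b1r1, Ad-GFP b2r1, Ad-ATP12A b1r1 and Ad-ATP12A b1r2, with collagen scores of −0.62 to 0.02 and 3 Xist-expressing libraries, against the other 4, with scores of 0.68 to 1.38 and 1 such library, so it points to a structure of the samples that the groups do not follow. For Ad-GFP against bleomycin 2 of 35 splits gave as many as the real 2 genes, and chance cannot be excluded. The highest other gave 744, with bleomycin b1r1, bleomycin b1r2, Ad-GFP b1r2 and Ad-GFP b2r2 on one side (scores 0.47 to 1.05, 0 Xist-expressing libraries) and scores of −0.62 to 0.87 with 2 such libraries on the other. So many genes point to a structure of the samples here too, but the scores of the sides overlapped, and what this split follows was not tested.

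For the counts of lists chance could not be excluded in any comparison. As many lists came from 2 of 35 splits for bleomycin against control (real 27, highest other 31), 21 for Ad-ATP12A against Ad-GFP (real 15, highest other 28), 19 for Ad-GFP against bleomycin (real 15, highest other 29) and 33 for Ad-ATP12A against bleomycin (real 10, highest other 25). The split by batch gave 18, 15 and 18 lists in the vector comparisons in that order, and 0 genes by limma in each. Its fit held a batch term, so these counts do not measure batch. In both batches 9 of the 15, 11 of the 15 and 7 of the 10 lists kept the pooled test's sign.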
